A study of Mus musculus with 6 samples.

How the data were processed

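RNA was sequenced from 6 mouse uterine samples of gestation day 13, 3 control and 3 labelled as deficient in PGR in the myometrium. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with a standard Illumina procedure. Whether the libraries keep strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not be told apart. The authors deposited FPKM values, 1 column per sample, rounded to 3 decimals, for 24964 gene symbols. Per the submitters' processing notes, cutadapt 2.7, STAR 2.7.0f, DESeq2 1.24.0 and genome build mm10 were used in making the data. The notes as used here give no role or order for these tools, and the counting program, the gene annotation, the treatment of reads shared by several genes and the formula behind FPKM are not given in the sources used here. All 6 columns were matched to samples by the names in the labels, and 0 columns were left unmatched. FPKM divides by gene length and library size only, so a few abundant transcripts can shift all other values of a library, and summed FPKM differed between libraries.

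The worth of 1 read was taken from low values. Between 0.1 and 0.5 FPKM, the ratio of 2 libraries' values for the same gene piled up at 1, with between 127 and 163 genes within 3% of it, against between 59.5 and 92.5 in neighbouring bands of equal width. Those genes were picked by their ratio, so the place of the peak was tested without such a choice. Over all genes between 0.06 and 0.5 FPKM (between 1877 and 2119 per library), the fullest bin of the ratio to control 1, 0.01 wide on the natural log scale, lay at 1 in 4 libraries and at 1.01 in deficient 2, with between 104 and 139 genes against a median of between 11 and 15 per bin. So 1 read was worth about the same in every column. From 142 genes with a single annotated transcript and values within 0.05 of a step from whole multiples of that step, with transcript lengths from GENCODE M21 (GRCm38), the library size behind the values came to about 36910000 reads (quartiles 36420000 and 37230000). It may be each library's depth or 1 common size used in the formula. Those genes were chosen because their steps agreed across libraries, and the estimate covers counting steps only. A floor of 3 reads on 1 kb is 0.0813 FPKM. Because what 1 read is worth depends on a gene length that the table does not hold, reads were not recovered for all genes and no count model was fitted here.

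The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), with the difference coded as labelled deficient minus control, all 6 samples and no covariate. Genes entered where the mean over the 6 samples was at least 1 FPKM, which left 12500 genes and set aside 12464, of which 5006 were listed at 0 in every sample. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold differences in log2 are on the log2(FPKM + 1) scale, which understates the change of genes with low values, while levels, SDs and times lower or higher are on the FPKM scale. Pgr was also compared by an exact two-sided permutation test.

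The 36 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Pgr, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups did not overlap, and in each list described up to 4 members with the smallest p. Gene models without a standard symbol were counted and not named, and some genes that the rule names, 1 of the 10 largest rises among them, are counted and not reported here, so the 9 rises given are not the full ranking. Genes outside the rule are said to have been chosen after their values were seen, and these include the members of a list beyond its first 4. Lists with at least 5 genes tested, 30 in number, were tested with camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, and adjusted over the 30 lists. Camera with an estimated correlation and fry were run beside it. Positions were taken from GENCODE M21, where 12387 of the 12500 symbols tested had one.

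The limma code was tested on simulated data for 3 control against 3 labelled deficient samples of 12500 genes. With 200 genes changed 2-fold, it recovered 82% of them with 9 false calls, with 200 genes changed 4-fold it recovered 94% with 7 false calls, and with no gene changed it made 0 calls. Noise was drawn for each gene on its own, with no effect shared within a library, so these rates may not hold for the real libraries. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a minimum mean of 5 FPKM, rescaling to a sum of 1000000, median-of-ratios scaling, quantile normalization, limma without the trend, limma with array weights, the replicate number as a block, and leaving out each library in turn. Leaving out the third library of both groups together was added after seeing the data. Figures were drawn with matplotlib 3.10.9.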

Results

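Gene expression was measured by RNA sequencing in uterine tissue taken around the sites where embryos had implanted, on day 13 of mouse gestation. The series held 6 libraries, 3 from control mice and 3 labelled as lacking the progesterone receptor (PGR) in the myometrium, the smooth muscle layer of the uterus. The progesterone receptor is a nuclear receptor that switches genes on and off when it binds progesterone, and its gene is Pgr. The comparison asks which transcripts differ in the uterus in mid-pregnancy when the receptor is missing from its muscle. The deposited table gives FPKM (fragments counted on a gene, scaled to the length of its model and to the size of the library) for 24964 gene symbols. The FPKM summed to between 357126 and 377091 per library, and between 12291 and 12592 genes per library reached 1 FPKM. In low values, 1 read was worth about the same FPKM in every library, and it corresponded to a library size of about 36910000 reads, with estimates for single columns between 36690000 and 36950000. The genes behind these estimates were chosen because their steps agreed across libraries, so the closeness of the columns is no independent evidence. Whether this size is the depth of each library or 1 common size used in the formula is not given in the sources used here. The depth of single libraries is therefore unknown. At that size, 3 reads on a gene of 1 kb are 0.0813 FPKM. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

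Pgr was not lower in the libraries labelled deficient. Pgr lies on chromosome 9 from 8899833 to 8968611 on the plus strand (GRCm38, the assembly also called mm10). Its level was 9.72, 8.33 and 12.08 FPKM in the 3 control libraries and 11.30, 12.41 and 7.73 FPKM in the 3 libraries labelled deficient. The means were 10.04 ± 1.90 (SD, n = 3) and 10.48 ± 2.44 FPKM (SD, n = 3), a difference in log2(FPKM + 1) of 0.05 with a standard error of 0.19 and a 95% confidence interval from -0.42 to 0.51. The limma adjusted p was 0.91. An exact two-sided permutation test gave p = 0.9, where 0.1 is the smallest value that 3 libraries against 3 allow. The sign of this difference was negative under 2 of the other scalings, -0.012 with median-of-ratios scaling and -0.0054 with quantile normalization. It was also negative without control 2 (-0.068), deficient 1 (-0.015) or deficient 2 (-0.078). It was larger and positive without control 3 (0.18), without deficient 3 (0.23), with array weights (0.21) and without control 3 and deficient 3 together (0.36, limma adjusted p = 0.088). The tissue was not restricted to muscle, and which part of Pgr was removed is not given in the sources used here, so a level over the whole gene is a weak check of the labels. Because the level of Pgr does not bear out the label, the second group is called the libraries labelled deficient throughout. Every direction given here rests on that label.

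Of 25 genes of the smooth muscle contractile apparatus, 19 were lower in the libraries labelled deficient. Actg2, the gamma actin of smooth muscle, was 4.72 times lower. Sfrp2, a secreted modulator of Wnt signalling, was at 6.22 times its control level. Of 12500 genes with a mean of at least 1 FPKM over the 6 libraries, 417 (3.34%) passed an adjusted p of 0.05 with limma, 168 higher and 249 lower in the libraries labelled deficient. Among them, 32 were higher and 86 lower by at least 1 on the log2 scale. For all 417, the 3 values of one group lay above the 3 of the other, which passing the test makes likely and which adds no support. Over the 12500 genes, 3626 (29.0%) were separated in that way, where chance gives 10% on average. Genes are not independent, and that share was not computed for other splits of the libraries. The median difference over all genes tested was 0.06 on the log2 scale.

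The split between higher and lower depended on the scaling. Rescaling every library to a sum of 1000000 gave 218 higher and 211 lower, median-of-ratios scaling 125 and 379, and quantile normalization 131 and 336. The third library of each group stood apart from the other two. Across the genes tested, which are not independent replicates, controls 1 and 2 correlated at 0.992 on the log2 scale and at 0.983 and 0.982 with control 3, and deficient 1 and 2 at 0.991 and at 0.976 and 0.971 with deficient 3. The most abundant transcript, Prap1, took 10.1% and 9.92% of the summed FPKM in control 3 and deficient 3 and between 6.08% and 7.22% in the others. With the third library of each group left out, an alternative chosen after seeing the data, 1275 genes passed, 619 higher and 656 lower. The count was 99 without control 1, 103 without control 2, 131 without deficient 1 and 188 without deficient 2. The number of higher genes was 85 without control 3 and 277 without deficient 3.

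Among the genes that rose, Sfrp2 (chromosome 3, 83766321 to 83774316) went from 2.93 ± 0.26 to 18.2 ± 4.9 FPKM (SD, n = 3 each), with a log2 difference of 2.26 (SE 0.19, limma adjusted p = 0.0044). Nmur2, a receptor for neuromedin U, rose by 2.09 on the log2 scale (SE 0.16), and Padi1, a peptidylarginine deiminase, by 2.07 (SE 0.25), from 40.8 ± 12.2 to 170.5 ± 31.6 FPKM. Next came Myl4, a myosin light chain of atrial and embryonic muscle (2.05), Alas2, the erythroid enzyme that starts haem synthesis (1.93), and Adamtsl2, a secreted matrix protein (1.79). Dio2, the deiodinase that activates thyroid hormone, and the tetraspanin gene Tspan1 both rose by 1.47, and Tmem200a by 1.44. The limma adjusted p of these 9 genes lay between 0.0033 and 0.029.

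Of the genes that fell, the largest change was that of Wfikkn2, a secreted inhibitor of myostatin (chromosome 11, 94235956 to 94246005), from 23.3 ± 10.6 to 1.03 ± 0.52 FPKM (SD, n = 3 each), a log2 difference of -3.52 (SE 0.33, limma adjusted p = 0.0057). The neuropeptide gene Npy fell by 2.91 on the log2 scale (SE 0.42), from 14.3 ± 8.3 to 0.884 ± 0.578 FPKM. The 10 largest falls included those of 3 genes for mast cell proteases, the chymases Mcpt4 (-2.43, SE 0.14) and Cma1 (-2.27, SE 0.19) and the carboxypeptidase Cpa3 (-2.38, SE 0.17), which went from between 7.48 and 7.98 FPKM to under 1 FPKM. Itih5, of the inter-alpha-trypsin inhibitor heavy chain family, fell from 64.6 ± 6.2 to 11.9 ± 1.8 FPKM. The fast troponin gene Tnni2 fell from 63.9 ± 14.9 to 11.7 ± 0.9 FPKM. Actg2 (chromosome 6, 83512905 to 83536265) fell from 2844 ± 354 to 602.6 ± 97.3 FPKM, with a log2 difference of -2.24 (SE 0.15, limma adjusted p = 0.0030). Mchr1, the receptor for melanin-concentrating hormone, and BC051019 completed the 10, at -2.17 and -2.16 (-4.07 and -3.77 with a pseudocount of 0.1). With 1 library left out, limma no longer called 5 of these 19 genes in at least 1 fit. Alas2 was lost in every such fit but the one without deficient 2, and at an adjusted p of 0.068 without control 3 and deficient 3 together and 0.056 with no filter. Myl4 was lost without control 1, deficient 1 or deficient 2, and Dio2 and Tspan1 without control 2, deficient 1 or deficient 2. Npy was lost without control 2, control 3, deficient 1 or deficient 2, and without control 3 and deficient 3 together (adjusted p = 0.055). The highest limma adjusted p among the fits with 1 library left out was 0.11, for Alas2.

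**Figure D1:**
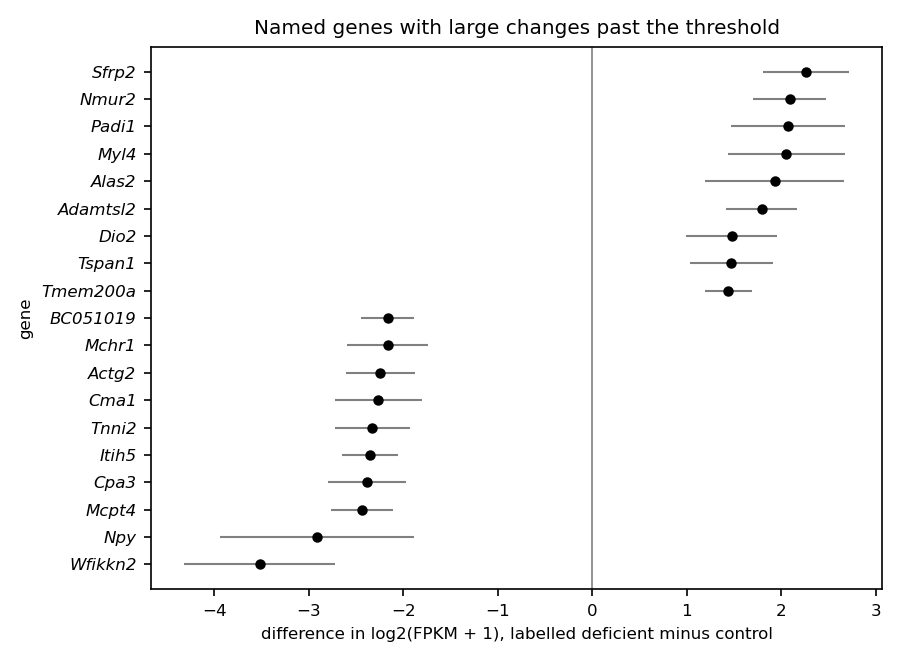
Difference in log2(FPKM + 1) between the 3 libraries labelled deficient and the 3 controls (horizontal axis) for 9 genes with large rises and the 10 genes with the largest falls past the threshold (vertical axis). Points are limma estimates and bars their 95% confidence intervals, which do not reach 0, with Wfikkn2 at -3.52 and Sfrp2 at 2.26.

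Of the 25 genes of the smooth muscle contractile list, all of them tested, 19 fell, 0 rose and 6 did not pass the test, and the median log2 difference was -0.89. The camera test with a preset correlation of 0.01 gave an adjusted p of 7.1e-28 for the list, and adjusted p = 0.27 with an estimated correlation. Besides Actg2, the members with the smallest p were Des, the muscle intermediate filament desmin (1037 ± 124 to 359.4 ± 38.6 FPKM), Tpm2, a tropomyosin (691.6 ± 37.4 to 262.4 ± 12.4 FPKM), and Csrp1, a LIM protein bound to the actin cytoskeleton (945.6 ± 73.5 to 383.7 ± 40.3 FPKM), each SD with n = 3. Chosen after their values were seen, Tagln (transgelin) fell by 1.17 on the log2 scale, Acta2 (smooth muscle alpha actin) by 0.97, Myh11 (smooth muscle myosin heavy chain) by 0.89 and Myocd, the coactivator that drives smooth muscle genes, by 0.73. Adjusted over the list alone, 22 genes fell and 1 rose, Mrvi1, at 0.54 on the log2 scale. The median stayed between -0.95 and -0.82 under the other scalings. The number of members called was 8 without control 1, 8 without control 2 and 10 without deficient 1. Acta2 was lost in those 3 fits (limma adjusted p up to 0.069) and with no filter (0.056), and Myocd without control 1, control 2 or deficient 2 (up to 0.076). Actin genes share much of their sequence, and how reads shared between Acta1, Acta2 and Actg2 were counted is not given in the sources used here, so the split between them is uncertain. In the same libraries, the mean log2 value of the epithelium list was 5.09 in the controls and 5.38 in the libraries labelled deficient, that of the endothelium list 3.97 and 3.98, that of the macrophage list 4.93 and 4.83, and that of the fibroblast list 6.07 and 5.94.

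**Figure D2:**
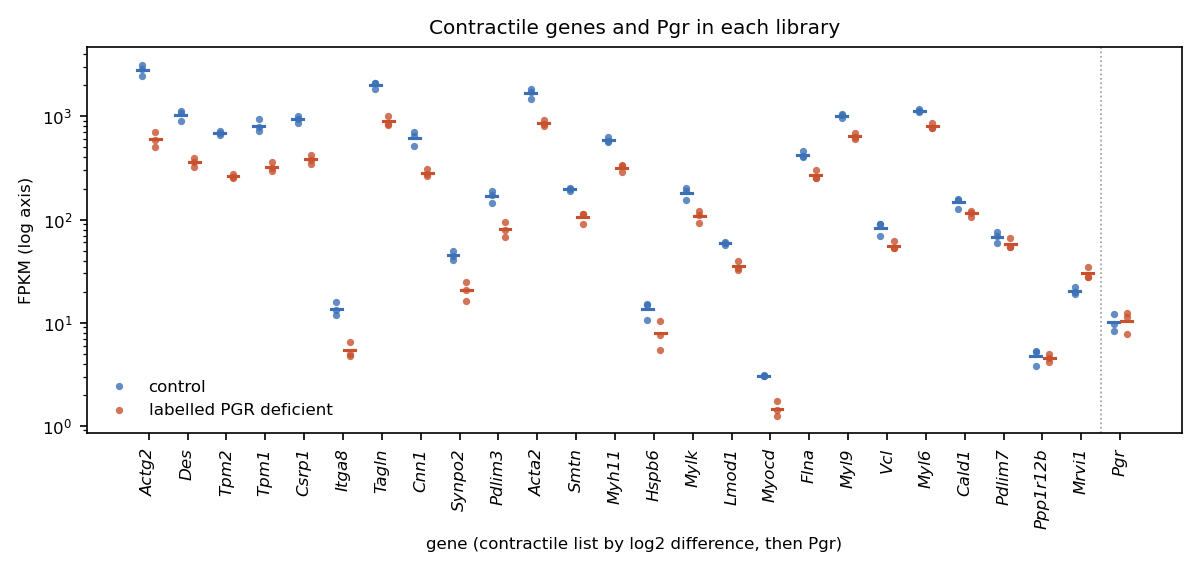
FPKM on a log axis (vertical) for the 25 genes of the smooth muscle contractile list, ordered by log2 difference, and for Pgr after the dotted line (horizontal). Points are the 3 libraries of each group and bars the group means, so that Actg2 falls from 2844 to 602.6 FPKM while Pgr stays at 10.04 and 10.48 FPKM.

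Of 22 ion channel and calcium handling genes of the myometrium tested, 5 fell and 0 rose. The list had a camera adjusted p of 3.7e-06, and adjusted p = 0.27 with an estimated correlation. Among the 5 were Stim1, the calcium sensor of the endoplasmic reticulum (-0.84, SE 0.08), Cacna1h, a T-type calcium channel (-0.71, SE 0.06), the plasma membrane calcium pump Atp2b4 (-0.82, SE 0.10) and the potassium channel Kcnj8 (-0.50, SE 0.06). With p adjusted over the list alone, 7 fell and 2 rose. Its median of -0.24 was -0.14 with no filter and -0.145 without deficient 1, and 2 genes were called without control 1, control 2 or deficient 1. Of these 4 genes, Kcnj8 lost its limma call without control 1, control 2, deficient 1 or deficient 2 (adjusted p up to 0.067) and Atp2b4 without control 1, control 2 or deficient 1 (up to 0.069). In the list of skeletal muscle genes, 5 of which were tested, Tnni2, Acta1 and Ckm fell and 0 rose. Acta1, the skeletal alpha actin, went from 113.3 ± 24.9 to 37.5 ± 5.6 FPKM (SD, n = 3 each). Ckm, the muscle creatine kinase, went from 2.36 ± 0.74 to 0.538 ± 0.236 FPKM. Adjusted over the list alone, 4 fell and 1 rose. This list had a camera adjusted p of 4.9e-04, and adjusted p = 0.32 with an estimated correlation. Its median was -1.12 over these 5 genes and -0.14 over 12 genes with no filter. Without control 1, control 2, deficient 1 or deficient 2, 1 gene was called. Acta1 was lost without control 1, control 2, deficient 1 or deficient 2 (limma adjusted p up to 0.066) and Ckm in every fit with 1 library left out except the one without control 3 (up to 0.14) and with no filter (0.062).

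Of 16 genes of uterine activation and contraction tested, 0 passed the limma threshold and 5 had an unadjusted p under 0.05 (Oxtr, Gja1, Ptger3, Fosl2 and Jun). Adjusted over the list alone, 1 rose, Oxtr, and 2 fell, Ptger3 and Jun. The camera adjusted p was 0.50. Oxtr, the oxytocin receptor (chromosome 6, 112473683 to 112489943), was at 11.3, 9.29 and 11.3 FPKM in the controls and at 34.0, 36.5 and 17.3 FPKM in the libraries labelled deficient. Its log2 difference was 1.31 (SE 0.27, limma adjusted p = 0.062), and it passed without deficient 3 (1.64, adjusted p = 0.0069) and without control 3 and deficient 3 together. Gja1, the gap junction protein connexin 43, differed by 0.24 (limma adjusted p = 0.15). Of 21 relaxation signalling genes tested, 1 fell, Plcl2, and 0 rose (camera adjusted p = 0.24). With p adjusted over the list alone, 3 fell and 1 rose.

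Of 23 genes tested that are known to respond to the progesterone receptor in the uterus, 3 fell and 0 rose. The camera adjusted p was 0.0025, and adjusted p = 0.27 with an estimated correlation. Plcl2, a phospholipase C-like protein, went from 9.68 ± 1.26 to 3.43 ± 0.40 FPKM (SD, n = 3 each, log2 difference -1.27). Fst, the activin-binding protein follistatin, went from 39.0 ± 5.2 to 16.9 ± 3.5 FPKM (-1.17), and Errfi1, an inhibitor of the EGF receptor, differed by -1.21 (SE 0.17). The median difference of the list was -0.03 and the mean -0.25. The median was -0.12 without control 1, -0.054 without control 3, -0.20 without deficient 1 and -0.18 without deficient 3. It was 0.0049 after rescaling to a sum of 1000000, -0.097 and -0.080 under the other 2 scalings, -0.098 with array weights and -0.15 with a minimum mean of 5 FPKM. The number of genes called was 1 without control 1, control 2, deficient 1 or deficient 2, 5 without control 3 and 7 without control 3 and deficient 3 together. Adjusted over the list alone, 8 fell and 2 rose. Fst lost its limma call without control 1, control 2, deficient 1 or deficient 2 (adjusted p up to 0.077), and Errfi1 in the same 4 fits (up to 0.066). Of 20 estrogen-responsive genes tested, 2 rose, Padi1 and the cell cycle inhibitor Cdkn1a (0.65, SE 0.10), and 0 fell, with a median of 0.32. The numbers adjusted over the list alone were 4 higher and 0 lower. Its camera adjusted p was 0.022 (0.054 without control 2), and adjusted p = 0.47 with an estimated correlation. Without deficient 3 the median was 0.53 with 4 genes called, without control 3 and deficient 3 together 0.57 with 6, and 1 gene was called without control 1, control 2, control 3 or deficient 2. Ltf, Lcn2, Greb1, Ramp3, Sprr2f and Padi2 lay above every control in deficient 1 and deficient 2 but below every control in deficient 3. Padi1, Cdkn1a, Esr1, Igf1, C3, Msx1 and Alox15 lay above every control in all libraries labelled deficient. These members were chosen after their values were seen. Cdkn1a lost its limma call in every fit with 1 library left out except the one without deficient 3 (adjusted p up to 0.12). Esr1, the estrogen receptor alpha, was at 26.6 ± 0.7 and 33.4 ± 2.4 FPKM and did not pass (limma adjusted p = 0.074). None of the 15 steroid receptor and coregulator genes tested passed (camera adjusted p = 0.47), and 2 of them rose when adjusted over the list alone. With fry this list passed, pointing up (fry adjusted p = 0.025).

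Of 18 decidual stroma genes tested, 1 fell, Fst, and 0 rose, with a median of -0.16. With p adjusted over the list alone, 6 fell and 1 rose. The camera adjusted p was 0.0060, and adjusted p = 0.27 with an estimated correlation. The median was -0.28 without control 3 or without deficient 1, -0.26 without control 3 and deficient 3 together and -0.24 with array weights. The number of genes called was 0 without control 1, control 2, deficient 1 or deficient 2, 2 without deficient 3 and 4 without control 3 and deficient 3 together. Prl8a2, a prolactin family hormone of the decidua, was at 154.7, 354.6 and 60.4 FPKM in the controls and at 5.44, 26.5 and 0.664 FPKM in the libraries labelled deficient. This wide spread left it short of the threshold (-4.50, SE 1.09, limma adjusted p = 0.089). Dio3, the deiodinase that inactivates thyroid hormone, was at 26.5 ± 17.1 and 4.93 ± 3.63 FPKM (limma adjusted p = 0.13). Its log2 difference of -2.33 became -1.14 (0.023) without control 3 and deficient 3 together. Of 26 matrix genes tested, 4 fell and 0 rose, with a median of -0.17. The camera adjusted p was 4.9e-04, and adjusted p = 0.47 with an estimated correlation. Fn1, fibronectin (chromosome 1, 71585520 to 71653200), went from 577.4 ± 16.1 to 142.4 ± 22.5 FPKM (SD, n = 3 each, log2 difference -2.02, SE 0.12). Postn (periostin) fell by 1.54 on the log2 scale, and the basement membrane collagens Col4a1 and Col4a2 by 0.46 and 0.47. Adjusted over the list alone, 9 fell and 3 rose. The number of genes called was 1 without control 1, control 2, deficient 1 or deficient 2 and 2 without control 3 or with no filter, where Postn (0.054) and Col4a1 (0.065) were lost. The list did not pass after quantile normalization (camera adjusted p = 0.13, median -0.084), nor did Col4a1 (limma adjusted p = 0.070). Col4a1 also did not pass after rescaling to a sum of 1000000 (0.062). Leaving out control 1, control 2, deficient 1 or deficient 2 ended the limma calls of Postn, Col4a1 and Col4a2, with adjusted p up to 0.15, as did leaving out control 3 for Postn and Col4a1.

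Of 16 epithelial genes tested, 2 rose and 0 fell, Krt19, a keratin, from 78.5 ± 11.0 to 164.1 ± 23.1 FPKM and Cdh1, E-cadherin, from 42.5 ± 1.4 to 57.8 ± 3.2 FPKM (SD, n = 3 each). The numbers adjusted over the list alone were 4 higher and 0 lower. The camera adjusted p was 0.034, and adjusted p = 0.27 with an estimated correlation. The list did not pass after rescaling to a sum of 1000000 (camera adjusted p = 0.064), without control 2 (0.12) or without deficient 2 (0.076). The number of genes called was 0 without control 2, control 3, deficient 1 or deficient 2 and 1 without control 1, while 5 were higher and 2 lower without deficient 3, and 7 and 2 without control 3 and deficient 3 together. Krt19 lost its limma call without control 2, control 3, deficient 1 or deficient 2 (adjusted p up to 0.078) and Cdh1 in every fit with 1 library left out except the one without deficient 3 (up to 0.12). Of 15 genes of pericytes and vascular mural cells, 5 fell and 0 rose, Des, Kcnj8, Aoc3 (-0.85), Mcam (-0.53) and Cspg4 (-0.56). Des stands on the contractile list and Kcnj8 on the ion channel list as well. The median of this list was 0.08, while its mean was -0.16 and the camera test pointed down. With p adjusted over the list alone, 5 fell and 1 rose. Its camera adjusted p was 0.042, and adjusted p = 0.27 with an estimated correlation. The call ended without control 2 (camera adjusted p = 0.054), control 3 (0.15) or deficient 2 (0.086) and without control 3 and deficient 3 together (0.099). It also ended with median-of-ratios scaling (0.095), quantile normalization (0.096), no filter (0.052) and array weights (0.10). The median ranged from -0.065 with a minimum mean of 5 FPKM to 0.14 after rescaling to a sum of 1000000. The number of genes called was 1 without control 1 or control 2, 2 without deficient 1 and 3 without deficient 2. Aoc3 lost its limma call without control 1 or control 2, and Mcam in every fit with 1 library left out except those without deficient 2 or deficient 3 (adjusted p up to 0.099).

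Of 15 fibroblast genes tested, 0 passed over all genes and 1 fell when adjusted over the list alone, Igfbp6 (350.2 ± 52.7 and 168.3 ± 42.6 FPKM, SD, n = 3 each). The next members by p went in both directions, Pdgfra at 0.43, Thy1 at -0.22 and Pi16 at 0.72 on the log2 scale. The median of the list was -0.18 and the camera adjusted p 0.014, and adjusted p = 0.27 with an estimated correlation. The median was -0.11 without control 1. The list did not pass without control 3 (camera adjusted p = 0.056), without control 3 and deficient 3 together (0.065) or after quantile normalization (0.20). Macrophage genes (16 tested, camera adjusted p = 0.064), neutrophil genes (6 tested, 0.24), endothelial genes (18 tested, 0.50) and genes of lymphocytes and dendritic cells (5 tested, 0.97) had 0 calls. Of 7 mesothelial genes, Krt19 rose (camera adjusted p = 0.50), and 2 rose when adjusted over the list alone. The lists of trophoblast (2 genes tested), fetal liver and yolk sac (4), erythroid cells (1), adipocytes (3) and uterine natural killer cells (3) had too few genes at 1 FPKM for a list test. With no filter on low values, the trophoblast list (18 genes, median -0.02) pointed down with a camera adjusted p of 8.4e-04, and adjusted p = 0.28 with an estimated correlation. Its 1 call was Ascl2, at 0.455 to 0.520 FPKM in the controls and 0.218 to 0.287 FPKM in the libraries labelled deficient (limma adjusted p = 0.034 in that fit). Chosen after its values were seen, Prl8a9, a prolactin family gene of this list, was at 9.89, 59.8 and 3.26 FPKM in the controls and at 0.433, 1.07 and 0.058 FPKM in the libraries labelled deficient, and did not pass (limma adjusted p = 0.18 with no filter and 0.12 in the main fit). The other 4 of these lists did not pass with no filter (lowest camera adjusted p 0.24). In the main fit, Alas2 of the erythroid list rose and Fabp4, a fatty acid-binding protein of the adipocyte list, fell by 1.09 on the log2 scale. None of the 13 mitochondrially encoded genes was among the symbols of the table used here.

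**Figure D3:**
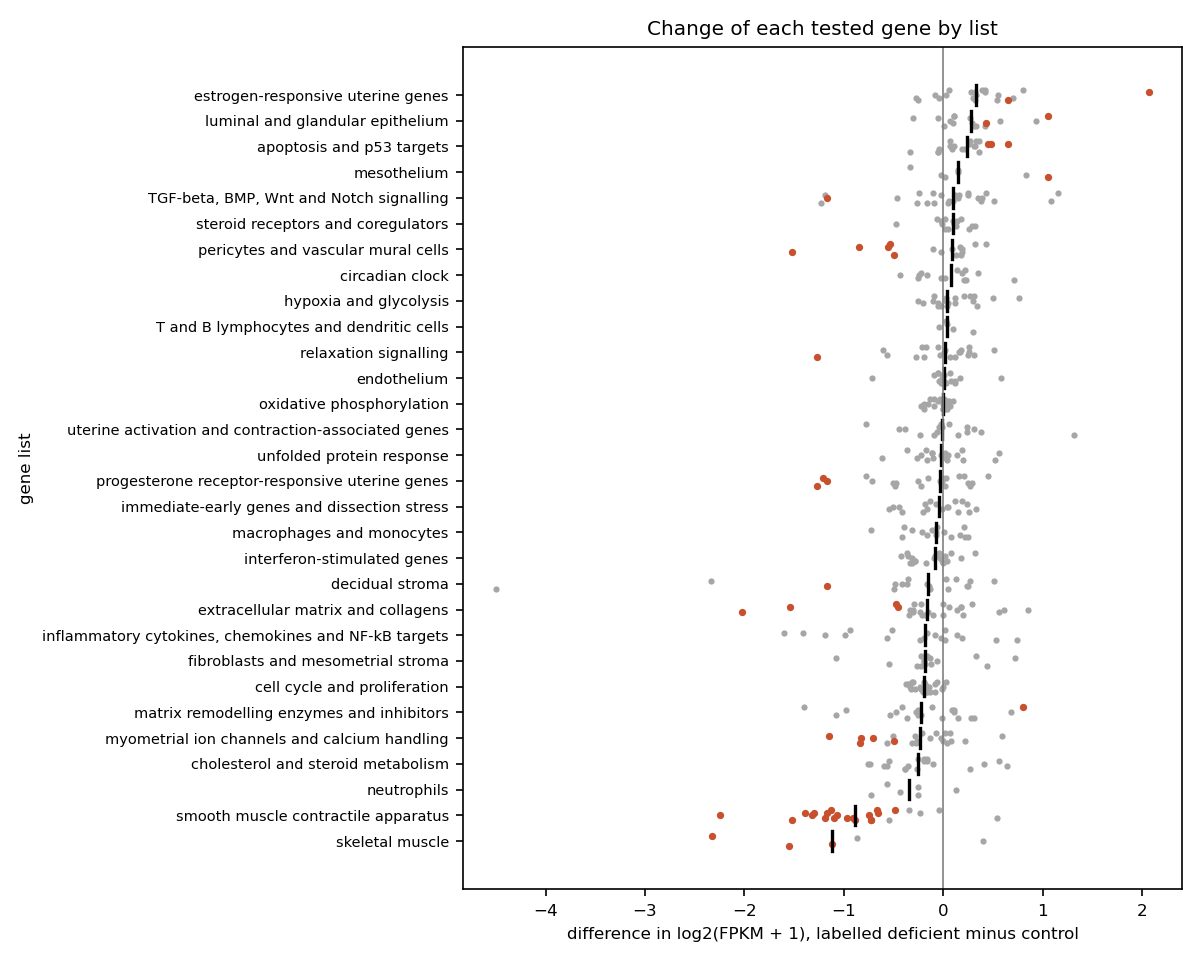
Difference in log2(FPKM + 1) between the libraries labelled deficient and the controls (horizontal axis, 3 libraries each) for the tested genes of 30 gene lists ordered by median (vertical axis). Orange points passed a limma adjusted p of 0.05, grey points did not, and black bars are list medians, with the contractile list at -0.89 and the skeletal muscle list at -1.12.

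Among lists of cell processes, 3 of 20 apoptosis and p53 target genes were higher, 0 lower and 17 did not pass, with a median of 0.24. The 3 were Pmaip1, the pro-apoptotic protein Noxa (0.47, SE 0.07), Cdkn1a, and Trp53inp1, a p53-induced nuclear protein (0.45, SE 0.08). Adjusted over the list alone, 5 rose and 0 fell. The camera adjusted p was 0.022, and adjusted p = 0.27 with an estimated correlation. It was 0.062 without control 3 and deficient 3 together. Pmaip1 lost its limma call in every fit with 1 library left out except the one without deficient 3 and Trp53inp1 in all 6 such fits (adjusted p up to 0.14), so that 0 genes of the list were called without control 1, control 2, control 3, deficient 1 or deficient 2. In 5 further lists the camera test pointed down while 0 genes passed the main limma test over all genes or adjusted over the list alone. The cell cycle list (25 genes, median -0.20) had a camera adjusted p of 0.0056, and adjusted p = 0.65 with an estimated correlation. It did not pass without control 1 (0.087), control 2 (0.10) or deficient 2 (0.081). Its median was -0.52 without control 3, -0.42 without deficient 3 and -0.72 without both, where 21 genes were lower, and it was -0.063 without control 1, -0.049 without control 2, -0.10 without deficient 1, -0.098 without deficient 2 and -0.56 with array weights. The cholesterol and steroid metabolism list (19 genes, median -0.25) had 0.0037, and adjusted p = 0.58 with an estimated correlation. It did not pass without deficient 3 (0.075), without control 3 and deficient 3 together (0.18) or with array weights (0.074), and 2, 2 and 3 genes were higher in those fits. Its median was -0.13 without control 2. Its members with the smallest p went in both directions. Srd5a1 differed by 0.64 on the log2 scale and Akr1c14 by 0.56, while Idi1 differed by -0.60. Fdps of the mevalonate pathway differed by -0.74, at 37.4 ± 8.2 and 22.2 ± 6.0 FPKM (SD, n = 3 each).

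The interferon-stimulated list (20 genes, median -0.09) had a camera adjusted p of 0.013, and adjusted p = 0.65 with an estimated correlation. Without deficient 3 its median was 0.03 (camera adjusted p = 0.69), without control 2 the adjusted p was 0.089, and without control 3 and deficient 3 together 0.13. It also did not pass with a minimum mean of 5 FPKM (0.15, median -0.019) or with array weights (0.080, median -0.029). The median was -0.18 without control 3, -0.19 without deficient 1 and -0.21 without deficient 2, and -0.0575, -0.14 and -0.15 under the 3 other scalings. The inflammatory cytokine list (18 genes, median -0.18) had 0.038, and adjusted p = 0.65 with an estimated correlation. It did not pass without control 1 (0.14), control 2 (0.12), deficient 1 (0.086) or deficient 3 (0.31), nor with median-of-ratios scaling (0.14), quantile normalization (0.13) or a minimum mean of 5 FPKM (0.16). Its median was -0.32 without control 3, -0.29 without deficient 2, -0.11 without control 1, -0.077 without deficient 1 and -0.097 without deficient 3. The oxidative phosphorylation list (22 genes, median -0.0061) had 0.038, and adjusted p = 0.66 with an estimated correlation. Its median was 0.04 after rescaling to a sum of 1000000, and it did not pass there (0.081), after quantile normalization (0.50), with a minimum mean of 5 FPKM (0.051), or without control 1 (0.49), deficient 2 (0.15) or deficient 3 (0.081). With 1 library left out, the median ranged from -0.10 to 0.048. Lists that did not pass the camera test were matrix remodelling (21 genes, 1 higher, adjusted p = 0.058), immediate-early genes (18, 0.063), the unfolded protein response (19, 0.064), TGF-beta, BMP, Wnt and Notch signalling (25, 1 lower, 0.51), the circadian clock (14, 0.64) and hypoxia and glycolysis (20, 0.96). The higher gene was the protease inhibitor Serpine2 and the lower one Fst. Serpine2 lost its limma call without control 1, deficient 1 or deficient 2 and with no filter, where 0 genes of the matrix remodelling list were called. Some lists without a call in the main fit passed in others. The matrix remodelling list passed with no filter (0.023), after rescaling to a sum of 1000000 (0.023) and without control 1, deficient 1 or deficient 2, the macrophage list without control 1 or deficient 2 (0.018 each), and the neutrophil list without deficient 2 (0.018). Without deficient 3, the immediate-early, unfolded protein and endothelial lists passed (0.017 each). The unfolded protein list also passed without control 1 (0.034), the immediate-early list after rescaling to a sum of 1000000 (0.044) and the endothelial list without control 3 and deficient 3 together (0.045). In the endothelial, TGF-beta, circadian and hypoxia lists, the camera test pointed down while median and mean lay above 0, in the relaxation list while the median did, and in the uterine activation list while the mean did. In all, 16 of the 30 lists tested passed with the preset correlation (10 without control 2) and 0 with an estimated one. With the preset correlation, the other ways to split the libraries 3 against 3 gave between 6 and 13 lists.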

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

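One alternative here, leaving out the third library of both groups together, was chosen after seeing the data. The counts of 417 genes (168 higher, 249 lower) and 16 lists stayed within 1.5 times of those values under both other pseudocounts, both other filters, rescaling to a sum of 1000000, quantile normalization and limma without the trend. Median-of-ratios scaling gave 379 lower genes. It shifted the differences down as a whole, with a median over all genes of 0.0064 on the log2 scale against 0.06 in the main fit. The share of higher genes among the calls was 24.8% with that scaling and 40.3% in the main fit. Array weights gave 1770 genes (1048 higher, 722 lower) and leaving out the third library of both groups 1275 (619 higher, 656 lower), where the first gives less weight to libraries that vary more and the second removes the pair that stood apart. With 1 library left out in turn, the count ranged from 99 to 525 genes, from 27 to 277 higher and from 71 to 248 lower, with fewer samples in each fit, and from 10 to 16 lists. The count was 99 without control 1, 103 without control 2, 131 without deficient 1 and 188 without deficient 2. With an estimated correlation, camera called 0 lists (4 at an unadjusted p under 0.05), and fry called 9. The lists called by fry were those of contractile, ion channel, skeletal muscle, progesterone-responsive, fibroblast, apoptosis, epithelial, pericyte and steroid receptor genes. The steroid receptor list is not among the 16. The difference in Pgr was -0.012 with median-of-ratios scaling and -0.0054 with quantile normalization, and from -0.078 to 0.23 with 1 library left out. It passed the threshold in none of these fits. Under those 2 scalings the median difference of all genes also moved down, from 0.06 to 0.0064 and 0.016. The cause of the sign changes with 1 library left out was not tested. The genes named by the rule and some of those chosen after their values were seen were followed through these fits. Apart from Pgr, none of the genes followed changed the tested direction, and neither did the 16 lists past the threshold. Of the 14 other lists, 5 did in at least 1 fit, and none passed there. Other genes mentioned in the text, such as Gata2, Kit and Hpgds, were not followed in this way. With the replicate number as a replicate block, 143 genes (31 higher, 112 lower) and 19 lists passed. Those lists included the macrophage (camera adjusted p = 0.010), neutrophil (0.025) and matrix remodelling (0.029) lists, which did not pass in the main fit. The replicate numbers did not pair the samples. Deviations of same-numbered libraries from their group means correlated across genes at -0.14, 0.08 and -0.13, and not every library correlated best with its own number. The planned count test on recovered reads was not run, since the worth of 1 read depends on gene lengths that the table does not hold. At a library size of about 36910000 reads, counting limits genes of 1 kb near 0.0813 FPKM.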

Other observations

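In this part, the tests of explanations and the counts over other splits of the samples were set down only after their results had been seen, as were the mast cell list and the genes named outside the lists. The other scalings, the gene lists fixed before and the interval of Pgr had been planned. Mast cells are leukocytes that store proteases and histamine in granules. Some of their genes were lower in the libraries labelled deficient beyond the 3 proteases among the largest falls. The mast cell list includes those 3, and no list test was run on it. Of 15 mast cell genes listed, 9 were tested and 4 fell with limma, Mcpt4, Cma1, Cpa3 and the tryptase Tpsb2 (5.56 ± 0.62 to 0.790 ± 0.244 FPKM, SD, n = 3 each), while 1 rose, the prostaglandin D synthase Hpgds, by 0.61 on the log2 scale. Kit, Gata2, Srgn and Hdc did not pass, and Gata2 also stands on the progesterone-responsive list. Counting genes too low to be tested, 8 of the 15 were lower in every library labelled deficient than in every control. Those include Fcer1a, a subunit of the IgE receptor, at 0.791, 1.27 and 0.926 FPKM in the controls and 0.026, 0.053 and 0.053 FPKM in the libraries labelled deficient. Tpsb2 and Tpsab1 are close copies, and how reads shared between them were counted is not given in the sources used here.

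Several genes outside the lists, chosen after their values were seen, also differed between the groups. Igfbp2, which binds insulin-like growth factors, fell from 621.3 ± 130.7 to 164.2 ± 21.1 FPKM (SD, n = 3 each). Hspb1, a small heat shock protein, fell by 1.58 on the log2 scale, Synm, an intermediate filament protein of muscle, by 1.65 and Itga5, the alpha subunit of the fibronectin receptor, by 1.64. Among genes that rose were Ltbp1, which binds latent TGF-beta (10.2 ± 1.1 to 26.7 ± 3.3 FPKM), the microfibril protein Mfap4 (79.7 ± 8.5 to 183.1 ± 19.7 FPKM) and Npr3, the clearance receptor of natriuretic peptides (0.301 ± 0.051 to 1.95 ± 0.22 FPKM). Rspo3 and Dkk2, secreted modulators of Wnt signalling, rose by 1.32 and 0.94. Dkk2 lost its limma call with any 1 library left out, with both other pseudocounts, with no filter and without the trend, and Rspo3 without control 1, control 3 or deficient 1 (adjusted p up to 0.15 and 0.086). Beside Alas2, the red cell anion exchanger gene Slc4a1 was at 0.065 to 0.096 FPKM in the controls and at 0.563 to 1.96 FPKM in the libraries labelled deficient, below the level tested. The adult haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were listed at 0 in all 6 libraries. The gland proteases Prss28 and Prss29 were at 86.6 and 207.1 FPKM in deficient 3 and at most at 7.46 and 43.5 FPKM in the other 5 libraries. Within 5 Mb of Pgr, 0 of 24 other genes tested passed limma (lowest adjusted p 0.12).

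The real split of the 6 samples gave 417 genes and 16 lists. Of the 10 ways to split them 3 against 3, 1 gave as many genes and 1 as many lists, in both cases the real split. The highest count of genes in another split was 39, and the highest count of lists, in a different split, 13. The lowest count of lists in another split was 6, so camera with the preset correlation called lists in every split. The number of list calls therefore says little on its own about the label. With 10 splits, a share under 0.05 cannot be reached.

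The fall of the contractile genes was set against 2 technical explanations. Scaling between libraries would have brought the list's median near 0 under another scaling, and the highest median under 3 other scalings was -0.82. Those scalings left the median difference of all genes between 0.0064 and 0.11. Differences between these scalings were thus too small to account for the fall, which is all that the comparison shows. A lower share of smooth muscle in the tissue sampled, and nothing else, would have raised the other cell types' lists alike, and the change of the epithelium list exceeded that of the fibroblast list by 0.42 (SE 0.13). That is the widest of 6 pairs of lists and lies 3.30 standard errors from 0, against a bound of 3. The bound was set after the value was seen, and the error rests on 3 libraries per group. The epithelium mean was 5.21, 5.30 and 5.62 in deficient 1, 2 and 3, and the list holds Prss28 and Prss29, which were highest in deficient 3. That comparison alone therefore cannot decide whether muscle share is the sole cause. A lower share alone would lower genes expressed only in muscle alike. Des fell by 1.52 (SE 0.13), Tagln by 1.17 (SE 0.11) and Myh11 by 0.89 (SE 0.09), while Mrvi1 rose by 0.54 (SE 0.11). The decidual and fibroblast means, which a lower share alone would not lower, differed by -0.51 (SE 0.13) and -0.13 (SE 0.03). Those of endothelium and macrophages differed by 0.0075 and -0.10. These values argue against muscle share as the sole change, for these genes and lists. A lower share of muscle together with other changes stays open. So does lower expression of these genes in muscle lacking the receptor, which was not tested here.

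The fall of some mast cell genes was set against a general loss of leukocytes. Such a loss was taken to lower the macrophage list by at least 1 on the log2 scale, a bound set after the values were seen. The mean of that list differed by -0.10 (SE 0.13), which goes against a fall of that size in macrophage genes. A smaller general loss would not reach the bound, so it cannot be excluded. The mean of the neutrophil list differed by -0.35, with 6 genes tested, and that of the lymphocyte and dendritic list by 0.08. A candidate explanation that some of the values go with is fewer mast cells in the tissue sampled. The receptor subunit genes Fcer1a and Ms4a2, outside the granule proteases, were lower too, with no overlap of the groups. Both were picked after their values were seen. The smaller ratio of their group means was 12.3, for Ms4a2, but the values of both genes in the libraries labelled deficient lie below the 0.0813 FPKM of 3 reads on 1 kb, so these ratios are imprecise. Against that floor they are 2.9 for Ms4a2 and 12.3 for Fcer1a. Kit and Gata2, which other uterine cells also express, did not fall. Hdc and Srgn did not pass either, and Hpgds rose. Of the genes too low to be tested, Gata1 and Slc18a2 were not lower in every library labelled deficient than in every control, while Il1rl1 was. Whether fewer cells follow from the genotype or from where the tissue was cut was not tested.

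That Pgr was not lower in the libraries labelled deficient was weighed against a mislabelled library. On the mean of the contractile list, the groups lay 0.63 apart on the log2 scale and the wider range within a group was 0.24. On this list, then, no single library sat with the other group. The list was already known to separate the groups under these labels, and it may follow the share of muscle sampled. The gap is therefore no independent check of the genotype of a library. It also says nothing of an exchange of both groups as a whole. Pgr RNA from cells outside the myometrium, or from the recombined allele, may hide a loss in muscle. The 95% interval of the log2 difference reached down to -0.42, which leaves room for a partial loss, and with no data on single cells or on the exons of Pgr these explanations cannot be told apart.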
